A study of Mus musculus with 2 samples.

How the data were processed

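The series holds total RNA from mononuclear cells of the colonic lamina propria of male Balb/c mice, with 1 array for germ-free and 1 array for SPF animals. Groups were taken from the sample titles. The labels do not say how many animals contributed to each sample. Per the labels, RNA was extracted with a Qiagen miRNA kit and labelled with Hy5 using an Exiqon labelling kit. The array platform, the miRBase release, the hybridisation conditions and the scanner software are not given in the sources used here.

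The deposited files hold 1 median spot intensity and 1 median local background intensity at 635 nm for each of 3200 spots. The deposited intensities carry no background subtraction or between-array scaling as far as the columns show. Per the file headers, the scans were taken at 3 gains and lines relate gain 1 to the other gains. The 3200 spots lie in 32 blocks with the same layout on both arrays and include 1900 mouse miRNA probes (12 of which name several miRNAs), 896 blank spots and 174 spots without a probe, besides negative, spike and other control probes. Each miRNA probe has 1 spot.

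The background of each array was the mean of its blank spots, 128.5 on the germ-free array (SD 4.53, 896 spots) and 158.3 on the SPF array (SD 5.33, 895 spots, after leaving out 1 blank spot that the file marks NG). The floor was the mean + 2 SD of the blank spots, a net intensity of 9.05 and 10.7. The floor is permissive, since 66.7% and 71.8% of the spots without a probe lay above it on the germ-free and the SPF array. Of the negative control spots, 65.6% and 56.25% lay above it. The blank mean was preferred to the local background after the files were seen. The local background followed the spot's own signal (Spearman correlation across miRNA spots 0.956 and 0.903, spots not being independent replicates), with a median of 63.7% and 44.2% of the signal at miRNA spots above an intensity of 500. Subtracting it raised the pooled SD of log2 values of repeated control spots from 0.0908 to 1.30. These repeats were 5 bright control probes with 8 spots on each array.

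Net intensities were scaled so that the median of the 1471 miRNAs above the floor on both arrays was the same, which multiplied the SPF values by 0.849. After scaling, the means of the 5 control probes differed by 0.07 to 0.22 on the log2 scale. Log2 SPF over germ-free was computed for each probe. A value under the floor was set to the floor for miRNAs above it on 1 array only, so that their log2 values are bounds. With 1 array per group no test between groups was run. The number of arrays limits the precision, and the repeated spots measure technical spread only.

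Counts at a fold of 2 or more were taken over miRNAs above the floor on both arrays. For 14 lists the member was the brighter arm of each precursor above the floor on at least 1 array. The list median was placed among 10000 random lists of the same size drawn from miRNAs in the same of 10 bins of mean log2 value, as a property of these 2 arrays. Percentiles under 2.5 or above 97.5 were treated as outside the central range. The lists, the floor, the fold threshold, the rule for naming miRNAs and most alternatives were fixed before the data were examined. The named miRNAs were the 12 with the largest values in each direction among shared miRNAs brighter than the median, the 10 brightest on each array, all detected members of the miR-200 family, intestinal epithelium, lymphocyte, myeloid and pan-leukocyte and immune activation lists, up to 4 members of every other list with the largest absolute values, and the 5 brightest above the floor on 1 array only. This gave 98 miRNAs.

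The alternatives were quantile, loess (span 0.4), equal total signal, widely expressed list and no scaling, no background subtraction, a pseudocount equal to the floor, a doubled floor, a floor at mean + 5 SD (for the numbers of detected miRNAs only), no floor, fold thresholds of 1.5 and 3, all arms in place of the brighter arm, and members above the floor on both arrays. Alternatives chosen after seeing the data were scaling on the spike controls, local background subtraction, a correction for the median of each block, a floor from the spots without a probe, and keeping the blank spot marked NG. A spot at or under its local background had no value under local background subtraction. Positions of miRNA genes come from GENCODE M21 on GRCm38, matched by name, since the files carry no coordinates.

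The procedure was tested on simulated arrays built from the germ-free intensities of the 1900 probes with the spread of the repeated and blank spots and 200 miRNAs changed per simulation, in 20 simulations. Among miRNAs above the floor on both simulated arrays, a true log2 value of 1.5 was called at least 2-fold for 98.2%. A true value of -1.5 was called for 93.8%, and a true value of 1, at the threshold itself, for 43.3%. These shares leave out miRNAs that fell under the floor, which more lowered miRNAs did (824 values at -1.5 against 989 at 1.5 over all simulations). Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots matplotlib 3.10.9.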

Results

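The comparison asked how miRNA levels in mononuclear cells of the colonic lamina propria differ between specific pathogen-free (SPF) mice, which carry a gut microbiota, and germ-free mice, which carry none. Each group was represented by 1 array, so no difference has a replicate error or a p-value, and the fold sizes and list medians below describe these 2 arrays. Of the 14 lists, the miR-200 family and intestinal epithelium had the highest medians on the SPF array with the blank spots as background, with miR-192-5p at 3.08-fold and miR-200b-3p at 2.88-fold the germ-free level. The lymphocyte miRNA miR-150-5p was 2.48-fold lower. The SD of log2 intensity between repeated bright control spots within an array was 0.0908, which gives a technical SD of 0.128 for a difference between single bright spots. In simulated arrays the SD of unchanged miRNAs was 0.27 over all shared miRNAs and 0.14 over those brighter than the median. The observed log2 values had an SD of 0.40 over all shared miRNAs and 0.36 over the brighter ones. The simulation holds only the spread within an array, so it does not tell spread between arrays from differences between the groups.

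Of 1900 mouse miRNA probes, 1539 were above the floor on the germ-free array and 1511 on the SPF array, with 1471 on both, 68 on the germ-free array only and 40 on the SPF array only. With the floor from spots without a probe, 1104 were above it on the germ-free array, 1081 on the SPF array and 1041 on both. Among the 1471 shared miRNAs, 23 were at least 2-fold higher and 21 at least 2-fold lower on the SPF array. Of these, 12 higher and 7 lower miRNAs were brighter than the median shared miRNA. Log2 SPF over germ-free differed from 0 by less than 0.5 for 83.1% of the shared miRNAs, and the values ranged from -1.88 to 2.01. In simulated arrays with no more than the technical spread of the repeated and blank spots, 8.95 unchanged miRNAs per simulation crossed 2-fold in either direction, none of them brighter than the median. The simulation leaves out the higher level of spots without a probe (mean + 2 SD of 165.8 and 202.2, against 137.6 and 169.0 for blank spots). More weak miRNAs than this may therefore cross by technical spread. The simulation also holds no spread between arrays, such as from RNA extraction, labelling or hybridisation. More bright miRNAs may cross for that reason too. The counts were 66 higher and 86 lower without a floor, and 6 higher and 3 lower without background subtraction. With the floor from spots without a probe they were 17 higher and 6 lower. With local background subtraction they were 97 and 51, with 3 of the 23 and 5 of the 21 among them. The balance depended on the scaling, with 39 higher and 9 lower without scaling, 30 and 12 with the widely expressed median set equal, and 17 and 30 with scaling on the spike controls.

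The miR-200 family, which represses the transcription factors Zeb1 and Zeb2 and is abundant in epithelia, was higher on the SPF array in all 5 members. The log2 values were 1.57 for miR-429-3p, 1.53 for miR-200b-3p, 1.26 for miR-200a-3p, 1.12 for miR-200c-3p and 1.09 for miR-141-3p. The list median of 1.26 lay at percentile 100 of 10000 random lists matched on signal, whose central 95% ran from -0.39 to 0.23. This family is the one that a published study of these samples is known to have followed up, so its direction is not independent evidence. In GENCODE M21 (GRCm38), Mir200b, Mir200a and Mir429 lie within the gene Ttll10 on its strand on chromosome 4, with Mir429 starting at 156053905 and Mir200b ending at 156055750. Mir141 and Mir200c lie on chromosome 6, between 124717914 and 124718390. Each of the family's 5 probes occupies 1 spot, and sequence similarity within the family allows cross-hybridisation. When each spot's own local background was subtracted, the family median was 0.82 and miR-200a-3p was at -0.14.

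The intestinal epithelium list, which was fixed to mark epithelial cells carried into the isolate, had a median of 1.11, also at percentile 100. Of its 6 detected members 4 were at least 2-fold higher, with miR-192-5p at 1.62, miR-194-5p at 1.36, miR-215-5p at 1.16 and miR-203-3p at 1.05. miR-375-5p, from a locus active in endocrine cells, was at -0.23, and miR-802-3p, close to the floor, was at -0.62. Each stands for its precursor as the brighter arm on these arrays, which need not follow the other arm. With all arms above the floor the list median was 1.05. miR-192 and miR-194 are encoded side by side on chromosome 19 (Mir192 at 6264844 to 6264932) and miR-194 and miR-215 on chromosome 1 (Mir215 at 185313581 to 185313692). The list median was 0.45 without background subtraction and 0.15 with local background subtraction.

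**Figure D1:**
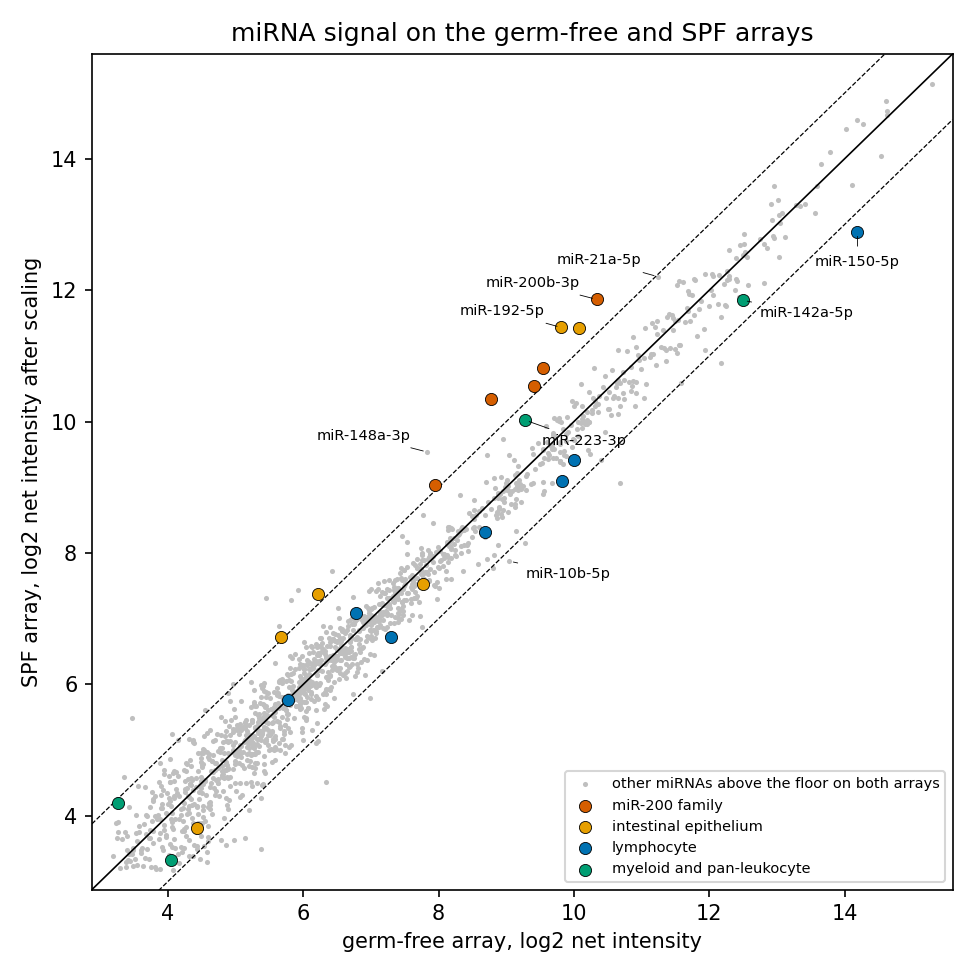
Each point is 1 of the miRNAs above the floor on both arrays, with log2 net intensity on the germ-free array on the x axis and log2 net intensity on the SPF array after scaling on the y axis. Coloured points are members of 4 lists, the solid line marks equal values and the dashed lines mark 2-fold differences. The 5 members of the miR-200 family lie above the upper dashed line and miR-150-5p lies below the lower one.

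The lymphocyte list had a median of -0.58, at percentile 0.05, with 6 of its 7 members lower on the SPF array. miR-150-5p, a miRNA of mature B and T cells that represses Myb, was at -1.31 and was among the 10 brightest miRNAs of the germ-free array. The other values were -0.73 for miR-181a-5p, -0.59 for miR-342-3p, -0.58 for miR-181c-5p, -0.36 for miR-155-5p and -0.02 for miR-181d-5p, while miR-181b-5p was at 0.31. miR-142a, which is expressed throughout the blood lineages, was lower in both arms, at -0.66 for miR-142a-5p and -1.01 for miR-142a-3p. The epithelial lists above moved the other way on the same arrays. With local background subtraction the lymphocyte median was 0.43, so its direction depends on how background is removed. That median leaves out miR-150-5p, which has no value because its local background exceeds its signal on the germ-free array. Repeated control spots spread by 1.30 under this setting. Without background subtraction the lymphocyte median was -0.29.

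The myeloid and pan-leukocyte list held members that went both ways, with a median of 0.04 at percentile 75.6. miR-223-3p, abundant in neutrophils and monocytes, was at 0.74, in contrast to miR-142a-5p. miR-147-3p at 0.93 and miR-511-5p at -0.72 lay close to the floor. Of the miRNAs induced by Toll-like receptor ligands or cytokines, 8 were measured, with a median of 0.09 at percentile 88.3. miR-21a-5p, one of the brightest of them, was at 0.96. miR-146a-5p and miR-146b-5p, which are induced through NF-kappa B, were at 0.07 and -0.02. The values were 0.11 for miR-132-3p, 0.10 for miR-187-5p and 0.07 for miR-212-3p. miR-147-3p at 0.93 and miR-155-5p at -0.36, named above, also belong to this list. The directions of miR-146a-5p and miR-146b-5p changed with the scaling, between -0.02 and 0.30 and between -0.11 and 0.21. The median of the myeloid list was -0.24 with local background subtraction and -0.048 with scaling on the spike controls, where that of the immune activation list was -0.0030.

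**Figure D2:**
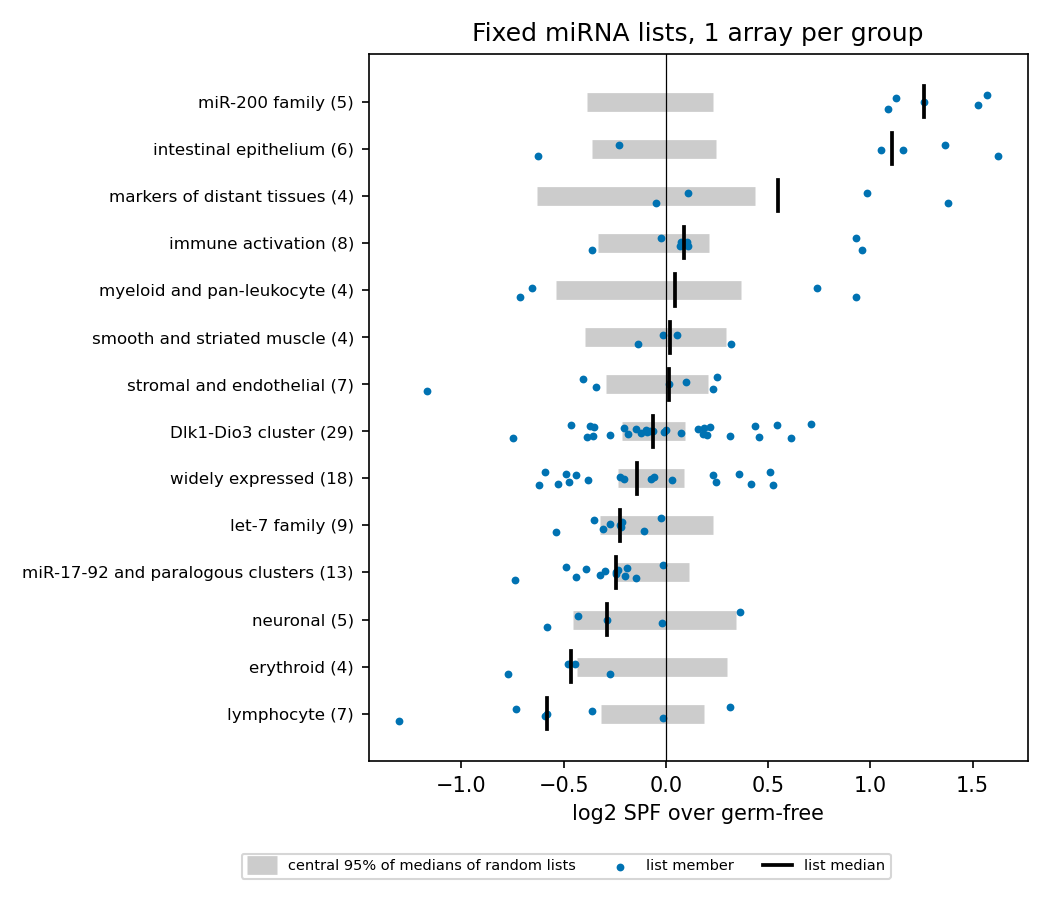
Log2 SPF over germ-free on the x axis for each detected member (blue points) of the 14 lists, with the number of probes in brackets, the list median (black bar) and the central 95% of medians of random lists matched on signal (grey band). The miR-200 family (1.26), intestinal epithelium (1.11) and the markers of distant tissues (0.55), a background check, lie above their bands and the lymphocyte (-0.58) and erythroid (-0.46) lists below theirs. The lymphocyte median is 0.43 with local background subtraction.

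Markers of other cell types that a lamina propria isolate can hold had lower medians than the epithelial lists with the blank spots as background, but not with local background subtraction, where the stromal median of 0.38 and the neuronal median of 0.20 exceeded the intestinal epithelium median of 0.15. The smooth and striated muscle list had a median of 0.02 at percentile 65.7, with miR-145a-5p at 0.32, miR-143-5p at -0.01, miR-133a-3p at 0.05 and miR-133b-3p at -0.14. The stromal and endothelial list had a median of 0.01 at percentile 72.8, its members running from miR-126a-3p at 0.25 through miR-214-3p at -0.34 and miR-100-5p at -0.41 to miR-10b-5p at -1.17. The erythroid list was lower in all 4 members, with a median of -0.46 at percentile 1.73, and held miR-144-3p at -0.77, miR-486a-3p at -0.48, miR-486b-3p at -0.45 and the bright miR-451a at -0.27. The muscle and stromal medians were -0.069 and -0.077 with scaling on the spike controls, and the muscle median was -0.11 with local background subtraction. In these lists too a member is the brighter arm, which need not follow the other arm. With all arms above the floor the muscle median was 0.16 and the erythroid median stayed at -0.46. The neuronal list had a median of -0.29 at percentile 10.6 with no member brighter than the median shared miRNA. Its values included miR-7b-3p at 0.36, miR-124-3p at -0.29, miR-128-3p at -0.43 and, under the floor on the SPF array, miR-153-5p at -0.58 or lower. The median was 0.023 with the floor from spots without a probe. The list of liver, heart and pancreas markers, a background check, had a median of 0.55 at percentile 98.9. Near the floor, miR-216a-3p was at 1.38 or more, miR-122-5p at 0.99 and miR-217-5p at 0.11, while the brighter miR-208a-5p was at -0.05. The median was 0.11 over members above the floor on both arrays, -0.0069 with the floor from spots without a probe and -0.064 with local background subtraction.

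The let-7 family had a median of -0.23 at percentile 8.42, with all 9 members lower, including let-7g-5p at -0.54, let-7i-5p at -0.35, let-7f-5p at -0.31 and let-7e-5p at -0.27. All 13 members of the cluster of miR-17 to miR-92a and its paralogs, which are linked to proliferation, were lower, with a median of -0.25 at percentile 2.75. miR-92a-3p was at -0.74, miR-106a-5p at -0.49, miR-19a-3p at -0.44 and miR-19b-3p at -0.39. Widely expressed miRNAs had a median of -0.14 at percentile 16.1 and went both ways, with miR-27b-3p at 0.53 and miR-15b-5p, miR-30e-5p and miR-15a-5p at -0.62, -0.59 and -0.53. The imprinted Dlk1-Dio3 cluster had a median of -0.06 at percentile 47.1, with miR-679-3p at 0.61, miR-410-5p at 0.54 and, under the floor on the SPF array, miR-376a-3p at -0.75 or lower. Without between-array scaling the let-7 median was 0.01 and the widely expressed median 0.095 (0.51 with local background subtraction), and with local background subtraction the median of these clusters was 0.094. The median of the Dlk1-Dio3 cluster was 0.17 without scaling, so the direction of these 4 medians depended on the processing.

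Outside the lists, miR-148a-3p was the highest on the SPF array among miRNAs brighter than the median, at 1.70 or 3.25-fold. It was followed by miR-196b-5p, encoded in the Hoxa9 locus, at 1.52, miR-6973b-3p at 1.46 and miR-182-5p at 1.31. miR-3971 was the lowest, at -1.61 or 3.05-fold lower. miR-10a-5p, encoded in a Hox cluster, was at -1.13, beside the nearly identical miR-10b-5p of the stromal and endothelial list at -1.17. miR-6980-5p was at -1.28, miR-3962 at -1.03, miR-195a-5p at -0.99, miR-5625-5p at -0.96, miR-721 at -0.88, miR-1927 at -0.85 and miR-5121 at -0.84. Without background subtraction miR-196b-5p, miR-6973b-3p and miR-182-5p were at 0.67, 0.61 and 0.65, and miR-721, miR-5625-5p, miR-10a-5p, miR-10b-5p and miR-3962 at -0.49, -0.42, -0.88, -0.87 and -0.74. With local background subtraction miR-182-5p was at -0.34, miR-10a-5p at 0.06 and miR-721 at 0.17, and miR-3971 was at -0.65.

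The brightest miRNA probe on both arrays was miR-7005-5p, at -0.15. miR-6366, miR-2137, miR-5126, miR-6240, miR-690, miR-3960 and miR-1902 were also among the 10 brightest on both arrays, at 0.09, 0.05, 0.27, 0.25, 0.41, 0.42 and -0.50. miR-1195 at -0.51 was among them on the germ-free array only, and miR-3154 at 0.32 and miR-2861 at 0.26 on the SPF array only. The 10 brightest probes held 22.5% of the net signal on the germ-free array and 23.9% on the SPF array. Of probes above the floor on 1 array only, the brightest lay near the floor and their log2 values are bounds against it. All 10 lie under the mean + 2 SD of the spots without a probe (intensities of 165.8 on the germ-free and 202.2 on the SPF array). Without background subtraction miR-216a-3p was at 0.16 and miR-126a-5p at -0.12. On the SPF array they were miR-216a-3p at 1.38 or more, miR-7077-3p at 1.20 or more, miR-452-3p at 0.98 or more, and miR-3063-5p and miR-188-3p, each at 0.93 or more. On the germ-free array they were miR-126a-5p at -1.38 or lower, miR-182-3p at -1.30 or lower, miR-6399 at -1.19 or lower, miR-6996-3p at -1.19 or lower and miR-3108-5p at -1.14 or lower. The other arms of miR-182 and miR-126a went the opposite way. miR-376b-3p of the Dlk1-Dio3 cluster, under the floor on the germ-free array, was at 0.71 or more.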

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

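The series of 22 probes named S-Probe1001 to S-Probe1022, which name no miRNA and which no comparison used, gave signal in 18 cases above the level of the spots without a probe on both arrays (mean + 2 SD, intensities of 165.8 on the germ-free and 202.2 on the SPF array), which is a signal in data outside the main measurement. The highest was 43225 on the germ-free array and 40437 on the SPF array.

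The tests of scaling, background and other cell types below were chosen after the values were seen. The test of position on the array and that of further epithelial miRNAs were written before their results.

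The miR-200 family and the intestinal epithelium list, pooled over 11 members, had a median log2 SPF over germ-free of 1.16 with a middle range from 1.07 to 1.44. The pooled median stayed at 1.07 or above over the scalings tried, which shifted the median shared miRNA by between -0.09 and 0.24. Shifts of that size could not bring it under the bound of 0.5 set for it. The pattern is thus larger than the differences between these scalings, but the test cannot exclude scaling in general. After correction for block medians the pooled median was 1.21, so differences between blocks did not bring it under 0.5. Effects within a block or at single spots cannot be seen, since each probe has 1 spot. Position on the array in general stays open. A lower leukocyte share that raises all other cell types alike needs the 20 muscle, stromal, endothelial, neuronal and erythroid members to be higher too. Their median was -0.20 (upper quartile 0.06). Without background subtraction the middle ranges did not overlap either (epithelial lower quartile 0.45 against upper quartile 0.026). The explanation stays open because the ranges overlapped with local background subtraction (lower quartile -0.14 against upper quartile 0.38). There, 9 epithelial and 18 other members had a value. Background handling cannot be excluded, because the pooled median with local background subtraction was 0.53, next to the bound of 0.5 set for it. The margin used for that bound was the technical SD of 0.128 with the blank background, while repeated control spots spread by 1.30 with local background subtraction. A larger share of epithelial cells in the SPF isolate may account for the pattern and stays open beside a difference in expression due to the microbiota, which was not tested. For 5 further epithelial miRNAs outside the lists (miR-196a-5p at 1.86, miR-96-5p at 0.58, miR-7a-5p at 0.37, miR-31-5p at 0.05, miR-183-3p at -0.42) the median was 0.37. A larger epithelial share was predicted to give a median above 0.5, which was not reached, while a negative median would have spoken against it. The value lies between and decides nothing, and the test could only have spoken against a larger share, not for it.

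The lymphocyte list had a median of -0.58, with miR-142a-5p at -0.66. The highest median over the scalings tried was -0.35. The largest shift of the median shared miRNA among them was 0.24, too small to reverse the list, so the test cannot exclude scaling in general. Background handling may account for the direction, since the median was 0.43 with local background subtraction, a setting under which repeated control spots spread by 1.30. Dilution of leukocyte RNA by other RNA stays open: all 4 erythroid, 9 let-7 and 13 miR-17 cluster members were also lower, though the let-7 median was 0.0101 and the miR-17 median -0.0101 without scaling, and the latter was 0.094 with local background subtraction, while miR-223-3p was at 0.74. The counted members are not independent measurements, since the let-7 miRNAs are nearly identical and can cross-hybridise, and Mir144 and Mir451a are neighbours on chromosome 11. A different mixture of leukocytes and a different level per cell also remain open and were not tested, since each group has 1 array.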

How the results depend on the processing

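The values of all 14 list medians and of the counts stand in the report. The median of the miR-200 family stayed positive under every alternative run on the list medians, with values from 0.82 to 1.498. That of intestinal epithelium ran from 0.15 to 1.34, and that of the erythroid list stayed negative (-0.55 to -0.23). The values of 0.82 and 0.15 came from local background subtraction, under which repeated control spots spread by 1.30. At that spread the sign of 0.15 cannot be read. The lymphocyte list stayed between -0.67 and -0.29 except with local background subtraction, where it reversed, and the distant tissue list changed sign under local background subtraction and with the floor from spots without a probe. Values that moved by more than the technical SD of 0.128 from bright control spots, and counts that moved by over 1.5 times, follow, and the cause was not tested except where the alternative shifts all miRNAs together. Relative to the scaled values the median shared miRNA moved by 0.24 without scaling and by 0.14 with the widely expressed median set equal. Spike scaling, local background subtraction, block correction, the floor from spots without a probe and the blank spot marked NG were chosen after seeing the data.

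With quantile scaling, the medians were neuronal -0.094 and distant tissues 0.68. With loess scaling, the median was neuronal -0.15. Without scaling, the medians were miR-200 family 1.498, intestinal epithelium 1.34, lymphocyte -0.35, myeloid 0.28, immune activation 0.32, muscle 0.26, stromal 0.25, erythroid -0.23, neuronal -0.052, let-7 family 0.0101, miR-17 clusters -0.0101, widely expressed 0.10, Dlk1-Dio3 0.17 and distant tissues 0.78. Then 39 miRNAs were at least 2-fold higher and 9 lower. With the widely expressed median set equal, the medians were miR-200 family 1.40, intestinal epithelium 1.25, lymphocyte -0.44, myeloid 0.18, immune activation 0.23, muscle 0.16, stromal 0.15, erythroid -0.32, neuronal -0.15, let-7 family -0.085, miR-17 clusters -0.11, widely expressed 0, Dlk1-Dio3 0.076 and distant tissues 0.69. Then 12 miRNAs were at least 2-fold lower. Without background subtraction, the medians were miR-200 family 1.10, intestinal epithelium 0.45, lymphocyte -0.29, neuronal -0.0012 and distant tissues 0.071. Then 6 miRNAs were at least 2-fold higher and 3 lower. With a pseudocount equal to the floor, the medians were neuronal -0.15 and distant tissues 0.33. Then 15 miRNAs were at least 2-fold higher and 10 lower. With the floor doubled, the medians were neuronal -0.0081 and distant tissues 0.095. Then 11 miRNAs were at least 2-fold lower. Without a floor, the median was distant tissues 0.13. Then 66 miRNAs were at least 2-fold higher and 86 lower. With local background subtraction, the medians were miR-200 family 0.82, intestinal epithelium 0.15, lymphocyte 0.43, myeloid -0.24, muscle -0.11, stromal 0.38, erythroid -0.27, neuronal 0.20, let-7 family -0.036, miR-17 clusters 0.094, widely expressed 0.51 and distant tissues -0.064. There, miR-182-5p was at -0.34, miR-200a-3p was at -0.14 and miR-10a-5p was at 0.064. Then 97 miRNAs were at least 2-fold higher and 51 lower. After correction for block medians, the medians were muscle 0.19, stromal 0.17, erythroid -0.32 and let-7 family -0.086. With the floor from spots without a probe, the medians were neuronal 0.023 and distant tissues -0.0069. Then 6 miRNAs were at least 2-fold lower. With all arms, the medians were miR-200 family 1.09, lymphocyte -0.45, muscle 0.16 and distant tissues 0.11. With members above the floor on both arrays, the medians were neuronal -0.15 and distant tissues 0.11. At a fold of 1.5, 68 miRNAs were higher and 112 lower. At a fold of 3, 4 miRNAs were higher and 3 lower. Spike scaling, equal total signal and keeping the blank spot marked NG moved no list median or count past these limits. Of the single named miRNAs, 915 values under the alternatives stayed within the technical SD, 398 moved beyond it and 3, of miRNAs at least 2-fold apart, changed sign. Sign changes of smaller values, such as miR-146b-5p, count among the others. The 23 higher miRNAs reported included all 6 that remained without background subtraction and 3 of the 97 found with local background subtraction. Alternatives on repeated spots were not run, since each miRNA has 1 spot. Signal over background limits the values near the floor, where 3 of the 4 distant tissue probes and, of the neuronal probes, miR-124-3p and miR-153-5p lie.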

Other observations

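The miRNA families in these paragraphs and the tests on them were chosen after the values were seen. The clustered pair miR-221 and miR-222, known to repress the kinase inhibitor p27, was higher on the SPF array, with miR-222-3p at 1.25 and miR-221-3p at 0.81. miR-196a-5p at 1.86 went with its near-identical relative miR-196b-5p at 1.52, both encoded in Hox clusters. miR-23a-3p, miR-23b-3p, miR-27a-3p and miR-27b-3p were at 0.35, 0.51, 0.42 and 0.53. The bright miR-29 family was lower, with miR-29a-3p at -0.70, miR-29c-3p at -0.67 and miR-29b-3p at -0.50, as were miR-101a-3p at -1.08 and miR-101b-3p at -0.84. The median of each of these families kept its direction under the scalings and without background subtraction, but their sizes moved. The median of the miR-221 and miR-222 probes went from 1.24 down to 0.47 over these settings, that of miR-196a-5p and miR-196b-5p from 1.69 to 0.70, and that of miR-101 from -0.96 to -0.26. With local background subtraction the median of the miR-221 and miR-222 probes was 0.22 and that of miR-196a-5p and miR-196b-5p 1.74. The medians were then -1.56 for miR-29 and -0.38 for miR-101, against -0.67 and -0.96. These values are over the probes that had a value. Of 13 miR-467 probes above the floor on both arrays, 11 were lower and 4 at least 2-fold lower, down to -1.82 for miR-467e-5p. Their median was -0.56, between -0.65 and -0.20 over the same settings, but it was 0.28 with local background subtraction.

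Neighbouring miRNA genes within 10 kb on 1 strand in GENCODE M21 gave 45 pairs. All members were above the floor on both arrays and brighter than the median. Pairs with the same number or within some related families, such as miR-200, were left out. Not every related pair was removed, since miR-290a with miR-291a and miR-290b with miR-292b stayed in. Pairs among the miR-466, miR-467 and miR-669 probes, such as miR-466c with miR-467b, stayed in too. Sequence similarity between paired probes was not tested as a reason for small differences. The pairs differed by a median of 0.20 on the log2 scale, against 0.30 for random pairings of the same 73 miRNAs. The observed median lay at percentile 1.99 of 10000 random pairings. This is consistent with 1 primary transcript setting the level of its miRNAs, as a hypothesis. Examples were miR-23b-3p and miR-27b-3p, which differed by 0.018, and miR-192-5p and miR-194-5p, which differed by 0.26, more than the median of the pairs. miR-182-5p at 1.31 and miR-183-3p at -0.42 were an exception, though these probes read opposite arms of their precursors. Of the pairs, 5 had both spots in the same block.

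Probes for miRNAs numbered 1000 or above held 69.3% of the net signal on the germ-free array and 70.4% on the SPF array, with 902 of the 1471 shared miRNAs.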
